A study of Mus musculus with 20 samples.

How the data were processed

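The values were those of the matrix deposited by the authors, for 20 arrays and 46089 probes. Per the labels, RNA came from mice in vivo, from cells in single cell suspension or after sorting, was extracted with RNAzol B and was labelled as biotinylated cRNA with an Ambion MessageAmp kit for Illumina arrays. The log2 values as deposited had been quantile normalized by the authors before deposit, which was read from the values, since every array held almost the same sorted values. The software and its background step were not given in the sources used here. The base of the logarithm was also read from the values. The largest, 15.19, corresponds to 37380 in linear units, under the limit of a 16-bit scanner (65535), where a natural logarithm would give 3.95e+06. Sorted values differed by at most 0.01 between arrays. The deposited table of values before normalization held 20 columns that matched no label, and these columns were not used here. No raw scans were analysed here.

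Group, chip and strain of each array were taken from the labels alone. The grafts and T-ALL were labelled as crosses of WB and C57BL/6, the wild-type arrays as C57BL/6 and the host spleens as WB, so strain differs along with group in the comparisons with wild-type arrays. Thymus grafts 1 and 2 and T-ALL 1 to 3 were on chip 1, grafts 3 and 4 and T-ALL 4 to 6 on chip 2, T-ALL 7 and the T-ALL marked Rag- on chip 3, and the wild-type and host arrays on chip 4. Chip was therefore treated as a batch in alternatives, and where no chip held both groups a chip difference could not be told from a group difference. Whether arrays of one label were separate mice was not given in the sources used here. The p values measure only the spread between these arrays, which may be partly technical. The number of arrays, at most 7 per group and 2 in several, limits precision.

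Gene symbols came from the annotation table of the array: 35667 probes had 1 symbol, 0 had several and 10422 had none. Symbols were brought up to date through a gene table, by gene ID for 28519 probes, accession for 2634, symbol for 2122 and synonym for 2336; 56 matched nothing, and 3273 symbols changed. This update was made after a first count of changed genes had been seen. Probes without a symbol were left out, 4058 of the 23639 that were above background on at least 2 arrays. The background mode of all values was 6.78 with SD 0.112 from the values below it, and the threshold, 3 SD above the mode, was 7.11 (139 in linear units). A gene was tested when a probe was above the threshold on at least 2 arrays, and the brightest such probe stood for it; 4623 of the 12710 genes tested had more than 1. Lmo1, Cd8a and Trp53 were not measured above this threshold.

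Group means of all 20 arrays were fitted with limma 3.58.1 in R 4.3.3, with 14 residual degrees of freedom, an intensity trend in the variance prior (prior degrees of freedom 3.13) and Benjamini-Hochberg adjustment within each comparison at 0.05. Gene lists, 30 in number and written from general knowledge, were tested with camera at a preset correlation of 0.01 between genes and adjusted over the 30; the estimated correlation and the rotation test fry were alternatives. The lists, comparisons, thresholds and alternatives were chosen before the data were examined, except where stated. A list of pancreatic acinar genes was added after the data had been seen. The use of the authors' normalized values with an intensity filter was itself settled late: the plan had been to process the values before normalization, with detection p values, and was dropped because those columns matched no label. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

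Apart from Xist and Eif2s3y, described after their values had been seen, genes named in the comparisons were chosen by rule. They were the 5 largest falls and rises among changed genes whose arrays did not overlap between groups, up to 4 changed members of each changed list or else its 2 brightest members, and a fixed set of genes tied to thymopoiesis and T-ALL, of which a member is not reported here. A fold change given as "at least" compared the brighter group's mean with the dimmer group's mean after each dim array was set to the threshold where it lay under it. Errors after ± are SD between arrays and SE is that of the limma contrast. Correlations with the erythroid list used permutation p values from 100000 permutations.

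Alternatives were background-subtracted values (mode subtracted, offset 16), centring on genes above background on all arrays, no intensity filter, a stricter filter, the mean of a gene's probes, symbols without update, robust moderation, array weights per group, models of only the compared groups, chip as random or fixed block, single chips, pooled T-ALL labels and leaving out each array. List medians without each array of a group of 2, and folds of named genes without each array, were also taken, with no test. On simulated arrays of the same layout with 100 genes changed 2-fold and 100 changed 4-fold, the model found 74 and 92 for T-ALL against grafts with 8 false calls. It found 51 and 88 with 5 false calls for grafts against wild-type thymus, and 42 and 79 with 0 false calls for host against wild-type spleen. The simulated genes varied independently, without the structure among samples seen on the real arrays, so these figures may not hold for them.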

Results

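Mouse thymus, thymus grafts and T cell acute lymphoblastic leukaemia (T-ALL) were profiled on Illumina expression arrays, to compare normal thymopoiesis, autonomous thymopoiesis in grafts and leukaemia. Per the labels, 4 arrays came from thymus grafts taken at 10 weeks, 7 from T-ALL and 3 from T-ALL marked Rag-, a mark that the labels do not explain. The other arrays were labelled wild-type thymus (n = 2, total thymocytes), wild-type spleen (n = 2) and host spleen (n = 2, total splenocytes). Values were the authors' log2 intensities after quantile normalization and had the same median, 6.95, on every array. A probe was taken as above background at 7.11, and 12710 genes were compared. A gene or list is said to have risen, fallen or changed only where the limma adjusted p was below 0.05.

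Before any comparison, the content of each array was set beside its label with lists of lineage genes. The T cell receptor (TCR) complex list, the CD3 chains and their signalling partners, averaged 12.03 ± 0.12 (SD) on the arrays labelled host spleen, 12.01 ± 0.55 on the grafts and 11.38 ± 0.12 on T-ALL. It averaged 10.06 ± 1.68 on the arrays labelled wild-type thymus and 10.66 ± 0.89 on those labelled wild-type spleen. The granulocyte list, products of neutrophil granules, averaged 11.48 ± 2.80 on the arrays labelled wild-type thymus, 12.50 ± 1.75 on wild-type spleen and 7.13 ± 0.10 on host spleen. Wild-type thymus 1 had the lowest TCR list mean, 8.87, beside a granulocyte mean of 13.47, and its nearest array was wild-type spleen 1 (r = 0.944). Wild-type thymus 3 had 11.25 and 9.50 for the same lists and was nearest to T-ALL 3 (r = 0.976).

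The arrays labelled host spleen 4 and 5 were nearest to each other (r = 0.993) and then to thymus graft 1 (r = 0.973 and 0.971). Their list of CD4/CD8 double-positive thymocyte genes stood at 11.69 and 11.54, against 8.29 and 10.21 on wild-type thymus 1 and 3. Wild-type spleen 3 was nearest to thymus graft 3 (r = 0.962) and correlated less with wild-type spleen 1 (r = 0.879). Its double-positive list (10.65), Rag1 (12.04) and Cd8b1 (14.39) lay above those of wild-type thymus 3 (10.21, 10.18 and 13.13), beside a granulocyte mean of 11.26. The content of these arrays thus contradicted the labels of spleen and thymus, for wild-type spleen 3 in its thymocyte genes, and nothing in the labels settled which was right. The groups were kept as labelled, no array was moved or dropped, and each comparison with the wild-type or host arrays is between arrays carrying those labels. Over all 20 arrays the nearest array carried the same label for 8. The mean correlation was 0.945 within labels and 0.917 between them (one-sided permutation p = 0.00332).

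**Figure D1:**
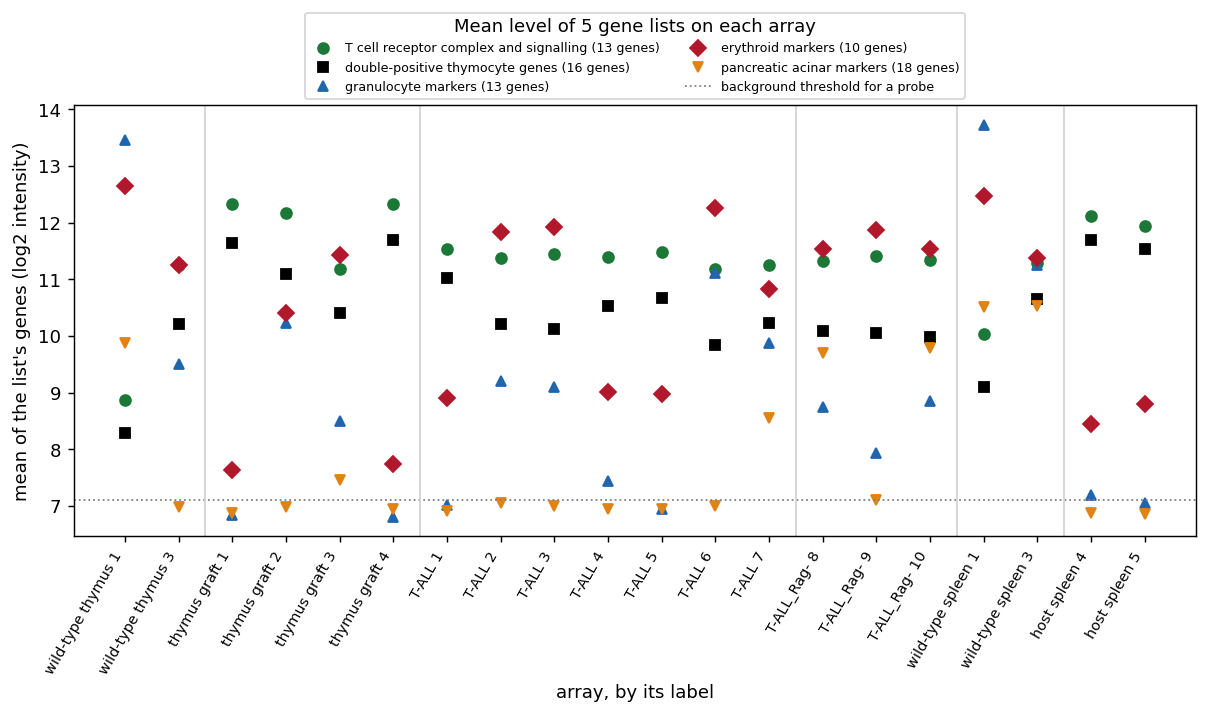
Mean log2 intensity (y axis) of the TCR complex, double-positive thymocyte, granulocyte, erythroid and pancreatic acinar lists on each of the 20 arrays (x axis, by label). Each point is 1 array; the TCR complex list averaged 12.03 on arrays labelled host spleen and 10.06 on arrays labelled wild-type thymus, and the granulocyte list 7.13 and 11.48.

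Fgf13, an intracellular fibroblast growth factor homologue, was at least 9.18-fold lower in T-ALL than in thymus grafts (7.40 ± 0.74, n = 7, against 10.66 ± 0.04, n = 4; log2 fold change -3.26, SE 0.31, adjusted p = 8.37e-05). It was above background on 3 of 7 T-ALL arrays. A fold given as at least compared the brighter group's mean with the dimmer group's after dim arrays were set to the threshold. Smoc1, a secreted calcium-binding matrix protein, was at least 5.26-fold lower (7.31 ± 0.49 against 9.78 ± 0.89, adjusted p = 0.00388; above background on 3 of 7). Hmgn3, which binds nucleosomes, was at least 4.57-fold lower (7.27 ± 0.37 against 9.53 ± 0.81, adjusted p = 0.0123; above background on 4 of 7). Cdk5r1, the activator of the kinase Cdk5, was 3.70-fold lower (8.01 ± 0.57 against 9.89 ± 0.33, adjusted p = 0.0106), and Cytip, which binds cytohesin and restrains leukocyte adhesion, 3.03-fold lower (11.36 ± 0.49 against 12.96 ± 0.54, adjusted p = 0.0339).

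Jdp2, a repressor of the AP-1 family, was 2.99-fold higher in T-ALL than in grafts (8.89 ± 0.54 against 7.31 ± 0.05; log2 fold change 1.58, SE 0.24, adjusted p = 0.0114). Fbln1, the matrix protein fibulin-1, was 8.78-fold higher (11.88 ± 0.33 against 8.75 ± 1.44; 3.13, SE 0.65, adjusted p = 0.0494). Graft 3 stood apart in Fbln1, at 10.89, without it the fold was 14.4, and the gene passed in 8 of 25 settings. Sumo3, a ubiquitin-like modifier, was 2.33-fold higher (11.64 ± 0.21 against 10.43 ± 0.37, adjusted p = 0.0339). Tmem106c and Dipk1b, a transmembrane and a kinase-like protein of little-known function, rose 2.28-fold and 2.20-fold (adjusted p = 0.0396 and 0.0430).

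Over all genes, 41 of 12710 changed between T-ALL and grafts, 12 higher and 29 lower, of which 23 changed at least 2-fold. For 32 of the 41 the arrays of the groups did not overlap, and 297 genes (2.34%) separated the groups completely, against 0.606% from chance order. All 41 kept their direction with chip as a block and within each chip that held both groups. The same arrays had picked these genes, which favours a kept direction, so this is no separate evidence. With chip as a block 0 passed in limma (1824 at unadjusted p < 0.05), on chip 1 alone 5 passed, 4 of them among the 41, and on chip 2 alone 0 passed (777 at unadjusted p < 0.05). Fgf13 was -3.21 (SE 0.36, adjusted p = 0.0601) with chip as a block, -3.57 (SE 0.27, adjusted p = 0.0345) on chip 1 and -2.85 (SE 0.63, adjusted p = 0.791) on chip 2. Fbln1 was 3.15, 3.49 and 2.81, Smoc1 -2.42, -3.01 and -1.84, Cytip -1.72, -1.97 and -1.46, and Jdp2 1.61, 1.40 and 1.83 in the same order. The count also rested on single arrays, with 2 genes after leaving out graft 1 or graft 4 and 1109 after leaving out graft 3. Xist, a gene expressed from the inactive X chromosome, was 10.18, 9.44 and 9.42 on grafts 1, 2 and 4 and 6.75 on graft 3. On T-ALL it was at most 7.76. The Y-linked gene Eif2s3y was 9.36 and 9.79 on T-ALL 2 and 7, at most 7.20 on the other T-ALL and at most 7.48 on grafts. On T-ALL 1, 4 and 5 both Xist (6.74, 6.82 and 6.80) and Eif2s3y (6.71, 6.59 and 6.77) were below background. T-ALL 2 had both above it (7.76 and 9.36). These genes therefore did not settle the sex of those arrays. Xist differed along with the groups, so a difference of sex was not separated from one of label.

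**Figure D2:**
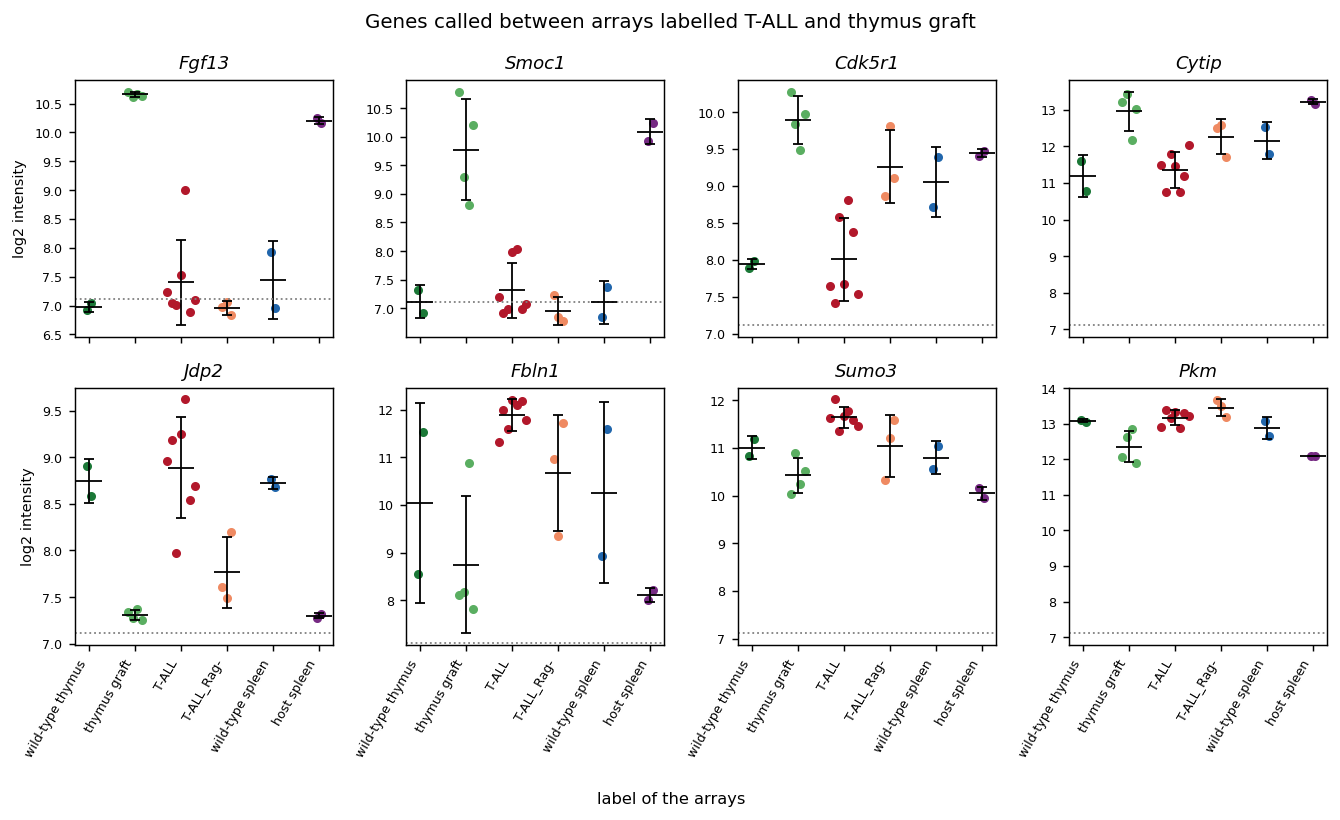
Log2 intensity (y axis) of 8 genes that changed between T-ALL and thymus grafts, by label (x axis). Points are arrays and bars are mean ± SD; the dotted line is the background threshold, 7.11, and Fgf13 averaged 7.40 in T-ALL and 10.66 in grafts.

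The list of double-positive thymocyte genes, active in thymocytes that rearrange TCR alpha, fell in T-ALL relative to grafts: 15 of 16 measured members were lower (median log2 fold change -0.88; adjusted p = 0.000238, or adjusted p = 0.761 with an estimated correlation). No member passed over all genes; 4 fell when adjusted over the list alone. Of its members, Cd4 was 7.73 ± 0.70 against 9.43 ± 1.07 (adjusted p = 0.0645), Rag1, a subunit of the V(D)J recombinase, 10.69 ± 1.04 against 11.97 ± 0.91 (0.331), and Cd8b1 14.01 ± 0.68 against 14.76 ± 0.35 (0.451). This list had adjusted p = 0.000102 with chip as a block, 0.000247 on chip 1 and 0.000564 on chip 2. The TCR complex list also fell, with 12 of 13 lower (median -0.44, adjusted p = 0.00727, or adjusted p = 0.817 with an estimated correlation). No member passed over all genes and 2 fell adjusted over the list alone. Cd3d differed by -0.23 (adjusted p = 0.876) and Cd3g by -0.54 (0.601). Graft 3 had Cd3d at 13.60, against 14.48 to 14.69 on the other grafts, which made its difference smaller. The TCR complex list had adjusted p = 0.000389 with chip as a block, 4.43e-06 on chip 1 and 0.0558 on chip 2.

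The cell cycle and DNA replication list rose in T-ALL, with 20 of 23 members higher (median 0.56, adjusted p = 1.82e-05, or adjusted p = 0.645 with an estimated correlation). No member passed over all genes and 9 rose adjusted over the list alone. Mki67, a marker of cycling cells, differed by 0.60 (adjusted p = 0.672; 0.35 to 1.31 with single grafts left out, the highest without graft 3) and the replication helicase subunit Mcm5 by 0.59 (adjusted p = 0.186). The list of MYC targets and ribosome biogenesis rose, with 15 of 16 higher (median 0.52, adjusted p = 0.000238, or adjusted p = 0.761 with an estimated correlation; 1 rose adjusted over the list alone). Eif4a1, a translation helicase, and Npm1, a nucleolar protein, differed by 0.15 and 0.33. Graft 3 was high in both, at 14.42 and 14.56, against 13.54 to 13.89 and 12.96 to 13.44 on the other grafts, which made these differences smaller. On chip 2 alone the adjusted p was 0.0539 for the cell cycle list and 0.255 for the MYC list, against 1.65e-07 and 6.88e-08 on chip 1 and 3.12e-05 and 0.000207 with chip as a block.

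The glycolysis and hypoxia list rose, with 9 of 14 members higher (median 0.32, adjusted p = 0.0134, or adjusted p = 0.404 with an estimated correlation). Pkm, pyruvate kinase, was 13.17 ± 0.20 in T-ALL and 12.36 ± 0.44 in grafts, 1.76-fold higher (adjusted p = 0.0494, passing in 6 of 25 settings). In this list 5 members rose adjusted over the list alone. The list of immediate-early and heat-shock genes fell, with 9 of 12 lower (median -0.44, adjusted p = 0.00329, or adjusted p = 0.404 with an estimated correlation; 4 fell adjusted over the list alone). Zfp36, a protein that speeds messenger RNA decay, was 2.73-fold lower (9.77 ± 0.08 against 11.22 ± 0.79, adjusted p = 0.0494, passing in 8 of 25 settings). Chip as a block, chip 1 and chip 2 gave adjusted p = 0.0156, 0.0179 and 0.0539 for glycolysis and 0.0131, 0.000721 and 0.145 for the immediate-early list. These lists were the 2 that also passed the rotation test, each with adjusted p = 0.0448.

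The Notch pathway and target list rose, with 13 of 15 members higher (median 0.67, adjusted p = 0.0201, or adjusted p = 0.761 with an estimated correlation; 1 rose adjusted over the list alone). Hes1, a direct Notch target that represses other regulators, was 9.54 ± 0.61 in T-ALL and 7.65 ± 1.06 in grafts (log2 fold change 1.88, SE 0.46, adjusted p = 0.0692). Dtx1, another target, was 11.33 ± 1.08 against 9.09 ± 2.33 (2.25, SE 0.86, adjusted p = 0.188), and the receptor Notch1 11.40 ± 0.60 against 10.18 ± 0.93 (1.22, SE 0.48, adjusted p = 0.204). Notch3 differed by 0.97 (adjusted p = 0.468). Graft 3 stood at the level of T-ALL, with a Notch list mean of 9.26 (9.05 in T-ALL), Dtx1 at 12.32, Notch1 at 11.54 and Hes1 at 9.24. Without it the differences were 3.32 for Dtx1, 1.67 for Notch1, 1.62 for Notch3 and 2.41 for Hes1. The list had adjusted p = 0.0315 with chip as a block, 4.31e-05 on chip 1 and 0.776 on chip 2.

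**Figure D3:**
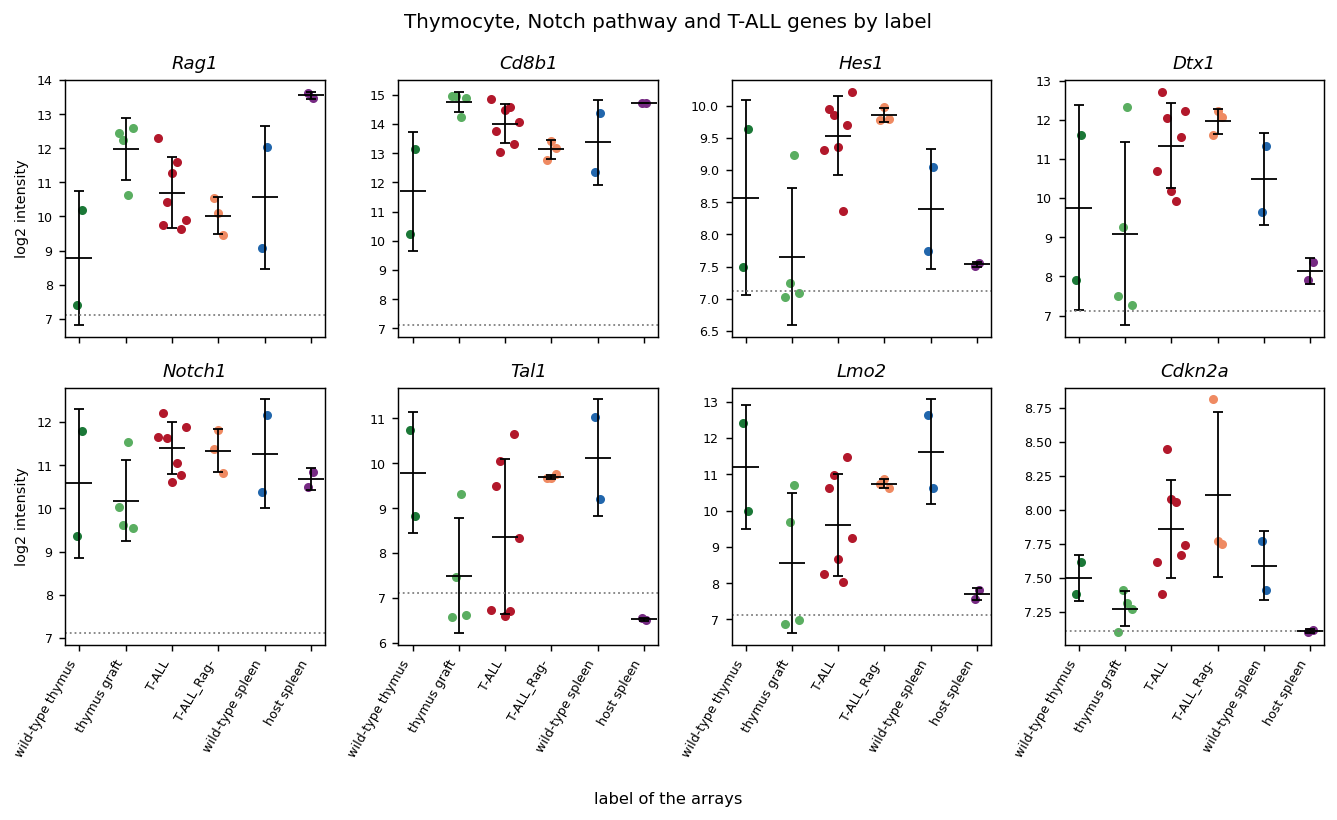
Log2 intensity (y axis) of genes tied to thymocyte maturation, Notch signalling and T-ALL, by label (x axis). Points are arrays, bars are mean ± SD and the dotted line is the background threshold, 7.11; Hes1 averaged 9.54 in T-ALL and 7.65 in grafts.

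Markers of other cells were present in unequal amounts. The macrophage list rose in T-ALL, with 16 of 16 members higher (median 0.63, adjusted p = 0.0497, or adjusted p = 0.853 with an estimated correlation), and 0 members passed in limma adjusted over the list alone. The erythroid list rose, with 10 of 10 higher (median 1.03, adjusted p = 0.0119, or adjusted p = 0.823 with an estimated correlation), again with 0 adjusted over the list alone. On grafts 1 to 4 the macrophage list stood at 6.94, 9.06, 10.19 and 6.95 and the erythroid list at 7.64, 10.40, 11.44 and 7.74. The size of each rise thus depended on which grafts were counted. Lyz1 and Vcam1, macrophage genes, differed by 1.46 (adjusted p = 0.443) and 1.90 (adjusted p = 0.403), with a range of 0.59 to 2.55 for Lyz1 and 1.04 to 3.19 for Vcam1 when single grafts were left out, the latter highest without graft 3. Beta-globin Hbb-b1 was 14.56 ± 0.42 against 11.95 ± 3.40 (adjusted p = 0.152), a difference of 2.61 that ranged from 1.61 to 3.60 in the same way. The macrophage list had adjusted p = 0.0225 with chip as a block, 8.88e-05 on chip 1 and 0.294 on chip 2, and the erythroid list 0.0315, 0.000686 and 0.412.

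The immature DN1-DN2 list did not pass (adjusted p = 0.0860) but rose with chip as a block (adjusted p = 0.0315) and on chip 1 (0.00211), and the T lineage factor list fell with chip as a block (adjusted p = 0.0315) and on chip 1 (0.0254). On chip 2 alone they had adjusted p = 0.255 and 0.110. These values used the preset correlation. An estimated correlation was not tried with chip, and over all arrays no list passed with it in camera (smallest adjusted p = 0.404). The T-ALL transcription factor list (12 measured) had adjusted p = 0.565. Tal1, an erythroid and T-ALL factor, was above background on 4 of 7 T-ALL arrays and 2 of 4 grafts, and differed by 0.86 (SE 0.78, adjusted p = 0.630). Its partner Lmo2 differed by 1.05 (SE 0.81, adjusted p = 0.553) and Lyl1, a related factor, by 0.85 (SE 0.40, adjusted p = 0.293). With single grafts left out Tal1 ranged from 0.56 to 1.47 and Lmo2 from 0.49 to 1.76. The receptor Kit of early progenitors differed by 1.16 (SE 0.53, adjusted p = 0.275), Myc by 0.67 (SE 0.28, adjusted p = 0.230) and the tumour suppressor Cdkn2a by 0.58 (SE 0.21, adjusted p = 0.157; 7.86 ± 0.36 against 7.28 ± 0.13). The list of DN3 and beta-selection genes had adjusted p = 0.709, although its member Egr2, a factor induced by TCR signals, was at least 4.12-fold lower (7.22 ± 0.25 against 9.30 ± 1.30, adjusted p = 0.0339; above background on 5 of 7 T-ALL arrays). Graft 3, with Egr2 at 7.36, lay within the range of T-ALL, and without it the bound was 6.46. Birc2, an inhibitor of apoptosis, was 1.88-fold lower (adjusted p = 0.0494, passing in 8 of 25 settings).

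Across the arrays that measured them, Tal1 and Lmo2 followed the erythroid list. Tal1 had r = 0.971 (permutation p = 1e-05, the smallest that the permutations could give, n = 13) and rank correlation 0.951. Without the 2 of its arrays farthest from the median erythroid level, r was 0.957. Lmo2 had r = 0.966 (permutation p = 1e-05, n = 18), rank correlation 0.972 and r = 0.950 without its own 2 farthest arrays. Within the T-ALL label Lmo2 had r = 0.967 over 7 arrays, and within chip 4 r = 0.982 over 6. For Tal1 no value was taken within a label or chip, since too few arrays were above background (4 of 7 in T-ALL). The permutations ran over arrays of all labels, so their p values include differences between labels. The platelet list followed them almost as closely, with r = 0.896 for Tal1 and 0.944 for Lmo2, and Lmo2 had r = 0.874 with the macrophage and 0.819 with the granulocyte list. Lyl1 had r = 0.57 with the erythroid list (permutation p = 0.0218, n = 16) and rank correlation 0.726 (permutation p = 0.00192). It had r = 0.643 without its own 2 farthest arrays and r = 0.457 within the T-ALL label. Its r was higher with the macrophage (0.797), platelet (0.753) and granulocyte (0.654) lists. All 3 relations with the erythroid list passed after adjustment over the 3 genes tested.

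**Figure D4:**
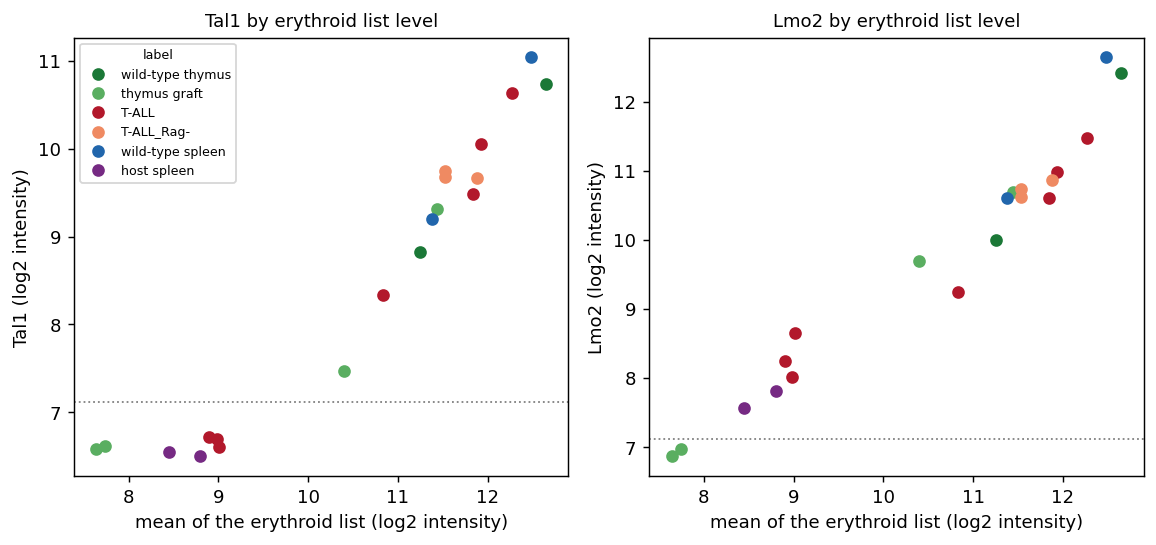
Log2 intensity of Tal1 and Lmo2 (y axis) against the mean log2 intensity of the erythroid list (x axis). Each point is 1 array, the dotted line is the background threshold, 7.11, and r was 0.971 for Tal1 and 0.966 for Lmo2.

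Tubb2b, a beta-tubulin, was 13.2-fold higher in thymus grafts than in the arrays labelled wild-type thymus (14.04 ± 0.19, n = 4, against 10.32 ± 0.38, n = 2; log2 fold change 3.72, SE 0.59, adjusted p = 0.0175). Fgf13 was below background on both thymus arrays and at least 11.7-fold higher in grafts (10.66 ± 0.04 against 6.98 ± 0.08, adjusted p = 0.00158). Nsg2, a vesicle protein known from neurons, was 9.80-fold higher (12.02 ± 0.93 against 8.72 ± 0.88, adjusted p = 0.0400, and 6.35-fold or 15.1-fold without wild-type thymus 1 or 3), Smoc1 at least 5.89-fold (9.78 ± 0.89 against 7.12 ± 0.29, adjusted p = 0.0297, above background on 1 of 2 thymus arrays) and the membrane skeleton protein Sptan1 2.80-fold (11.13 ± 0.28 against 9.64 ± 0.23, adjusted p = 0.0121). Lrp4, a receptor of the LDL receptor family, was at least 3.29-fold lower (7.12 ± 0.20 against 8.90 ± 0.56, adjusted p = 0.0121). Dst, a cytoskeletal linker, and Cldn12, a claudin, were at least 1.81-fold and 1.69-fold lower (adjusted p = 0.0400 and 0.0175); each of these 3 was above background on 1 of 4 grafts. Eps8, an actin regulator, and Stard13, a protein with a lipid-binding START domain, were below background on all 4 grafts and at least 1.56-fold and 1.21-fold lower (adjusted p = 0.0400 and 0.0306).

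These were the 10 genes of 12710 that changed, 5 higher and 5 lower, 7 of them at least 2-fold, with 2578 at unadjusted p < 0.05. In each the arrays of the groups did not overlap, and 2371 genes (18.7%) separated the groups, against 13.3% from chance order. No chip held both groups, so no within-chip value exists. With chip as a random block 279 genes passed. The estimated correlation within chips was negative there (-0.12), which narrows the error of a contrast between chips. The higher count is therefore no allowance for chip. Centring the values gave 7 genes, 5 higher and 2 lower. Leaving out 1 array gave from 1 (graft 1) to 1437 genes (wild-type thymus 3). The 5 higher genes also stood near graft level on the arrays labelled host spleen 4 and 5. Fgf13 was 10.25 and 10.16 there, Smoc1 9.93 and 10.24, Nsg2 12.49 and 12.27, Sptan1 10.99 and 11.11 and Tubb2b 13.32 and 13.39. High levels of these genes were thus not particular to grafts.

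The TCR complex list was higher in grafts in 13 of 13 members (median 1.95, adjusted p = 7.17e-10, or adjusted p = 0.372 with an estimated correlation; 11 rose adjusted over the list alone). The double-positive list was higher in 15 of 16 (median 2.22, adjusted p = 2.18e-09, or adjusted p = 0.372 with an estimated correlation; 14 rose and 1 fell adjusted over the list alone). Cd8b1 stood at 14.76 ± 0.35 against 11.69 ± 2.04 (log2 fold change 3.07, adjusted p = 0.0894) and Rag1 at 11.97 ± 0.91 against 8.79 ± 1.97 (3.19, adjusted p = 0.114). Cd3e, a signalling chain of the TCR, differed by 2.00 (adjusted p = 0.122) and Cd3g by 2.15 (adjusted p = 0.121). These 2 lists passed the rotation test, each with adjusted p = 0.0277. The T lineage factor list rose (12 of 12 higher, median 1.07, adjusted p = 7.51e-06, or adjusted p = 0.372 with an estimated correlation; 6 adjusted over the list alone), with Bcl11b, required for T commitment, at 1.99 (adjusted p = 0.125) and Ets1 at 1.89 (adjusted p = 0.143). Without wild-type thymus 1 the medians were 0.58 for the TCR complex, 0.95 for double-positive genes and 0.11 for T lineage factors. The differences were then 1.63 for Cd8b1, 1.79 for Rag1, 0.20 for Cd3e, 0.28 for Cd3g, 0.60 for Bcl11b and 0.01 for Ets1. The array then left, wild-type thymus 3, was nearest to T-ALL 3 (r = 0.976), so it may not show normal thymus.

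Smaller rises were those of the DN3 and beta-selection list (11 of 17 higher, median 0.22, adjusted p = 0.0284, or adjusted p = 0.457 with an estimated correlation; 4 adjusted over the list alone) and the apoptosis list (10 of 12 higher, median 0.30, adjusted p = 0.0231, or adjusted p = 0.384 with an estimated correlation; 2 adjusted over the list alone). Of the apoptosis genes, the survival factor Mcl1 differed by 0.60 (adjusted p = 0.338). The cell cycle list fell (21 of 23 lower, median -0.43, adjusted p = 0.000772, or adjusted p = 0.456 with an estimated correlation; 1 adjusted over the list alone), with Mki67 at -2.42 (adjusted p = 0.144; -3.14 without graft 3). MYC targets fell (16 of 16 lower, median -0.69, adjusted p = 0.00126, or adjusted p = 0.535 with an estimated correlation), with 0 in limma adjusted over the list alone. Without wild-type thymus 1 the median of the DN3 list turned to -0.07, and without wild-type thymus 3 the medians were -0.06 for the cell cycle and -0.28 for MYC targets. The apoptosis median was 0.29 and 0.20 without the one and the other.

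Markers of other cells were lower in grafts than in the arrays labelled wild-type thymus. The macrophage list fell in 16 of 16 members (median -3.01, adjusted p = 3.65e-10, or adjusted p = 0.372 with an estimated correlation; 15 adjusted over the list alone), with Vcam1 at -4.38 (adjusted p = 0.141) and Lyz1 at -3.06 (adjusted p = 0.190). The granulocyte list fell in 13 of 13 (median -3.70, adjusted p = 1.13e-06, or adjusted p = 0.372 with an estimated correlation; 10 adjusted over the list alone), with the calcium-binding proteins S100a8 and S100a9 at -4.12 (adjusted p = 0.317) and -4.00 (adjusted p = 0.230). The erythroid list fell in 10 of 10 (median -2.62, adjusted p = 5.78e-05, or adjusted p = 0.372 with an estimated correlation) and the platelet list in 8 of 8 with median -1.93 (adjusted p = 0.000136, or adjusted p = 0.372 with an estimated correlation; 4 adjusted over the list alone). In the same direction, the list of immature DN1-DN2 genes was lower in 15 of 15 members, with median -1.23 (adjusted p = 7.51e-06, or adjusted p = 0.372 with an estimated correlation; 2 adjusted over the list alone). Its member Fcer1g, an Fc receptor chain also made by myeloid cells, stood at -4.11 (adjusted p = 0.125). The T-ALL factor list was lower in 10 of 12, with median -0.49 (adjusted p = 0.0226, or adjusted p = 0.372 with an estimated correlation), with Tal1 at -2.29 and Lmo2 at -2.65 (adjusted p = 0.246 and 0.197). The type I interferon list was lower in 13 of 13, with median -1.03 (adjusted p = 0.000246, or adjusted p = 0.372 with an estimated correlation; 1 adjusted over the list alone), with the antiviral gene Rsad2 at -3.63 (adjusted p = 0.149). Notch1 differed by -0.40 (adjusted p = 0.787). The erythroid and T-ALL factor lists had 0 members passing in limma adjusted over the list alone, and no member of any list passed over all genes. The interferon result rested on wild-type thymus 1 (list mean 11.04, against 8.13 on wild-type thymus 3 and 8.21 in grafts), and without that array its median turned to 0.20. Without it the medians were -1.55 for macrophages, -1.52 for granulocytes, -0.70 for platelets, -0.36 for DN1-DN2 genes and -0.12 for T-ALL factors. The differences without it were -3.53 for Vcam1, -1.56 for Lyz1, -2.77 for Fcer1g, -3.52 for S100a8, -2.56 for S100a9, -1.33 for Tal1, -1.45 for Lmo2, -1.99 for Rsad2 and -1.62 for Notch1, which turned to 0.83 without wild-type thymus 3 instead.

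Against the arrays labelled wild-type thymus, Tubb2b was 10.9-fold higher in T-ALL (13.77 ± 0.73, n = 7, against 10.32 ± 0.38, n = 2; log2 fold change 3.45, SE 0.54, adjusted p = 0.0215). Lrp4 was at least 3.12-fold lower (7.16 ± 0.33 against 8.90 ± 0.56, adjusted p = 0.0190; above background on 3 of 7 T-ALL arrays). Dst was at least 1.86-fold lower (adjusted p = 0.0215; above background on 2 of 7) and Cldn12 at least 1.66-fold lower (adjusted p = 0.0215; above background on 1 of 7). These 4 genes were all that changed, 1 higher and 3 lower, with 1795 at unadjusted p < 0.05. No chip held both groups. With chip as a random block 17 genes passed, at the same negative correlation within chips (-0.12), so this count does not allow for chip either. With only these groups in the model 0 passed in limma (1459 at unadjusted p < 0.05), and leaving out 1 array gave from 0 to 1313.

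T cell lists rose in T-ALL against these arrays, which also served in the comparison with grafts, so likeness between the comparisons is no separate evidence. The TCR complex list was higher in 13 of 13 members, with median 1.39 (adjusted p = 4.28e-07, or adjusted p = 0.399 with an estimated correlation; 10 adjusted over the list alone), with Cd3d at 1.91 (adjusted p = 0.220). The double-positive list was higher in 15 of 16, with median 1.02 (adjusted p = 4.87e-05, or adjusted p = 0.399 with an estimated correlation; 2 adjusted over the list alone), with Cd8b1 at 2.32 (adjusted p = 0.164) and Rag1 at 1.91 (adjusted p = 0.316). The T lineage factors were higher in 12 of 12, with median 0.90 (adjusted p = 6.2e-05, or adjusted p = 0.399 with an estimated correlation) and the DN3 list in 14 of 17, with median 0.82 (adjusted p = 0.00143, or adjusted p = 0.399 with an estimated correlation). Notch1 differed by 0.82 (adjusted p = 0.560). The T lineage and DN3 lists had 0 members passing in limma adjusted over the list alone. These rises rested on wild-type thymus 1, since wild-type thymus 3 stood at 11.25 for the TCR complex, within the range of T-ALL, and at 10.21 for double-positive genes, against 10.38 in T-ALL. Without wild-type thymus 1 the medians were 0.06 for the TCR complex, 0.18 for double-positive genes, -0.07 for T lineage factors and -0.20 for the DN3 list. The differences were then 0.88 for Cd8b1, 0.51 for Rag1, -0.20 for Cd3d and -0.40 for Notch1. Wild-type thymus 3, the array then left, was itself nearest to T-ALL 3. Its Hes1 (9.64), Dtx1 (11.60) and Notch1 (11.80) stood near the T-ALL means (9.54, 11.33 and 11.40). The values without wild-type thymus 1 therefore do not show that T-ALL equalled normal thymus.

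Markers of other cells again fell. The macrophage list was lower in 16 of 16 members, with median -2.30 (adjusted p = 3.77e-09, or adjusted p = 0.399 with an estimated correlation; 10 adjusted over the list alone) and the granulocyte list in 13 of 13, with median -3.24 (adjusted p = 1.59e-06, or adjusted p = 0.399 with an estimated correlation), with S100a8 at -3.37. The platelet list was lower in 8 of 8, with median -1.39 (adjusted p = 0.00143, or adjusted p = 0.536 with an estimated correlation) and the erythroid list in 10 of 10, with median -1.25 (adjusted p = 0.0132, or adjusted p = 0.761 with an estimated correlation). The interferon list was lower in 12 of 13, with median -1.23 (adjusted p = 5.03e-05, or adjusted p = 0.399 with an estimated correlation; 2 adjusted over the list alone), with Rsad2 at -2.85 (adjusted p = 0.307). The DN1-DN2 list was lower in 15 of 15, with median -0.61 (adjusted p = 0.000154, or adjusted p = 0.399 with an estimated correlation), with Kit at -0.07. The T-ALL factor list was lower in 9 of 12, with median -0.40 (adjusted p = 0.0392, or adjusted p = 0.399 with an estimated correlation), with Tal1 at -1.42 (adjusted p = 0.532). Apart from the macrophage and interferon lists, these lists had 0 members passing in limma adjusted over the list alone, and no member of any list passed over all genes. Without wild-type thymus 1 the interferon median turned to 0.09 and that of DN1-DN2 genes to 0.02. The others were then -0.89 for macrophages, -0.78 for granulocytes, -0.48 for erythroid genes, -0.10 for platelets and -0.20 for T-ALL factors. The differences were then -1.21 for Rsad2, -2.77 for S100a8 and -0.47 for Tal1. These values too set T-ALL against wild-type thymus 3 alone, the array nearest to T-ALL 3.

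Tubb2b, Lrp4, Dst and Cldn12 changed in the same direction in grafts and T-ALL against wild-type thymus: 4 genes shared of 10 and 4, where 0.000393 higher and 0.00118 lower were expected for independent sets. The same 2 thymus arrays served in each comparison and could not be divided between them. In 50 simulations of shared controls without group differences the mean overlap was 0.02 genes and the largest 1. With no differences simulated, hardly any gene can pass in either comparison, so a small overlap was fixed in advance. Neither these simulations nor the values for independent sets show what shared arrays would give among genes that passed. Over all genes the fold changes correlated at r = 0.815, against 0.721 in those simulations. Their covariance was 0.297, against 0.0944 simulated, a difference of 0.203. Part of the resemblance over all genes may thus come from the shared arrays, whose labels are in doubt. The simulations do not show what the rest comes from.

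No gene changed between T-ALL marked Rag- (n = 3) and T-ALL (n = 7): 0 of 12710 in limma, with 652 at unadjusted p < 0.05 and a smallest adjusted p of 0.896. Rag1 was 10.03 ± 0.54 against 10.69 ± 1.04 (log2 fold change -0.67, SE 0.71, adjusted p = 0.925), and Rag2, its partner subunit, was above background on 1 of 3 Rag- arrays (-0.61, adjusted p = 0.910). Kit was 7.58 ± 0.30 against 9.35 ± 1.11 (-1.77, SE 0.58, adjusted p = 0.901), and the interleukin-2 receptor chain Il2ra 9.48 ± 0.68 against 8.11 ± 1.23 (1.37, SE 0.67, adjusted p = 0.901). Tal1 was 9.70 ± 0.04 against 8.36 ± 1.73 (1.34, SE 0.86, adjusted p = 0.910).

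MYC targets were higher in T-ALL marked Rag- in 16 of 16 members (median 0.43, adjusted p = 0.000457, or adjusted p = 0.945 with an estimated correlation), with 0 in limma adjusted over the list alone and Npm1 at 0.43. The erythroid list was higher in 10 of 10 (median 0.94, adjusted p = 0.0348, or adjusted p = 0.945 with an estimated correlation), with Hbb-b1 at 0.26 and again 0 members adjusted over the list alone. All 3 Rag- arrays and 1 T-ALL array were on chip 3. With chip as a block 13 genes passed, all lower, the MYC list had adjusted p = 0.00655 and the erythroid list 0.400. On chip 3 alone 0 genes passed in limma (1397 at unadjusted p < 0.05), and the lists had adjusted p = 0.000224 and 9.72e-05. Markers of other cells moved as well: in both of these fits the macrophage list had a median of 0.86 and the granulocyte list a median of -1.68. With chip as a block or on chip 3 alone, each of these values sets the 3 Rag- arrays against the single array T-ALL 7, so it cannot tell a difference of the labels from one of that array.

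No gene changed between the arrays labelled wild-type thymus and wild-type spleen (n = 2 each): 0 in limma, with 664 at unadjusted p < 0.05 and a smallest adjusted p of 0.167. Cd8b1 was lower on the thymus label, 11.69 ± 2.04 against 13.37 ± 1.45 (adjusted p = 0.936). Mzb1, a plasma cell chaperone, was below background on both thymus arrays and at least 27.6-fold lower (7.08 ± 0.05 against 11.90 ± 3.39, adjusted p = 0.807), a bound that rested on wild-type spleen 1 (14.30, against 9.50 on wild-type spleen 3) and was 5.23-fold without it. The interferon list was higher on the thymus label in 13 of 13 members (median 1.33, adjusted p = 2.17e-07, or adjusted p = 0.402 with an estimated correlation; 1 adjusted over the list alone), with Rsad2 at 1.33 and the interferon-induced protease Usp18 at 2.31 (adjusted p = 0.947). The macrophage list was higher in 13 of 16 (median 1.02, adjusted p = 0.0452, or adjusted p = 0.954 with an estimated correlation). Wild-type thymus 1 alone was high, with an interferon list mean of 11.04 against 8.13 on wild-type thymus 3 and 8.25 and 7.98 on the spleen arrays. Without it the medians were 0.03 for interferon and -0.32 for macrophages. The differences were then -0.23 for Cd8b1, -0.30 for Rsad2 and 0.92 for Usp18.

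The double-positive list was lower on the thymus label than on the spleen label in 15 of 16 members (median -0.52, adjusted p = 0.0203, or adjusted p = 0.954 with an estimated correlation). The TCR complex list was lower in 11 of 13 (median -0.60, adjusted p = 0.0428, or adjusted p = 0.954 with an estimated correlation), with Cd3g at -0.43. Also lower were the mast cell list (8 of 9 members, median -1.22, adjusted p = 1.56e-06, or adjusted p = 0.402 with an estimated correlation; 5 adjusted over the list alone) and the plasma cell list (7 of 7, median -0.46, adjusted p = 0.000295, or adjusted p = 0.402 with an estimated correlation; 3 adjusted over the list alone). The fibroblast list was lower in 10 of 12, with median -1.16 (adjusted p = 0.000496, or adjusted p = 0.555 with an estimated correlation) and the endothelium list in 10 of 10, with median -0.77 (adjusted p = 4.78e-05, or adjusted p = 0.555 with an estimated correlation). The macrophage, double-positive, TCR complex, fibroblast and endothelium lists had 0 members passing in limma adjusted over the list alone. Without wild-type thymus 1 the double-positive and TCR complex medians turned to 0.39 and 0.58 and the difference of Cd3g to 1.44. Without wild-type spleen 1 the medians were 0.02 for mast cells, -0.06 for plasma cells, -0.49 for fibroblasts and -0.28 for endothelium, so these falls rested on that array. Leaving out 1 array gave from 7 to 207 genes.

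Neutrophil granule genes were far lower on the arrays labelled host spleen than on those labelled wild-type spleen (n = 2 each). Lactoferrin, Ltf, was at least 108-fold lower (6.93 ± 0.13 against 13.87 ± 1.79; log2 fold change -6.93, SE 1.80, adjusted p = 0.0475). The antimicrobial peptide Camp was at least 74.1-fold lower (7.06 ± 0.01 against 13.32 ± 1.58, adjusted p = 0.0487), the chitinase-like Chil3 at least 47.9-fold (6.85 ± 0.13 against 12.70 ± 2.45, adjusted p = 0.0497) and the granulocyte product Retnlg at least 30.3-fold (7.00 ± 0.06 against 12.04 ± 1.89, adjusted p = 0.0357). The pancreatic enzyme Cela2a and the lipase cofactor Clps were at least 38.3-fold and 27.5-fold lower (adjusted p = 0.0358 and 0.0151). Each of these was below background on both host arrays. Without wild-type spleen 1 the bounds were 44.8-fold for Ltf, 34.2-fold for Camp, 14.4-fold for Chil3 and 12.0-fold for Retnlg. Of 14 settings, Ltf passed in only 5, Camp in 4, Chil3 in 2 and Retnlg in 9.

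T cell genes were higher on the host spleen label. Trbv13-1 and Trbv1, segments of TCR beta, were at least 30.5-fold (12.04 ± 0.06 against 6.89 ± 0.04, adjusted p = 0.0445) and 13.4-fold higher (10.86 ± 0.11 against 6.93 ± 0.08, adjusted p = 0.0293), although probes of related segments may cross-hybridize. Themis, which acts in thymocyte selection, was at least 6.53-fold higher (10.79 ± 0.26 against 8.03 ± 1.46, adjusted p = 0.0294; above background on 1 of 2 wild-type arrays), Egr2 at least 6.22-fold (adjusted p = 0.0298; above background on 1 of 2) and Lcp2, the adaptor SLP-76, 3.22-fold (adjusted p = 0.0289). Csrnp1, a nuclear protein, was 8.82-fold higher (12.34 ± 0.01 against 9.20 ± 0.03, adjusted p = 0.0322). Gm5815, a predicted gene above background on 1 of 2 wild-type arrays, and the pseudogene Pisd-ps3, whose probe may share sequence with relatives, were 10.4-fold and 8.91-fold higher (adjusted p = 0.00362 and 0.0117). Without wild-type spleen 1 Themis was 3.33-fold and Gm5815 6.21-fold higher. The receptor Slamf6 was 3.78-fold higher (adjusted p = 0.0410), but with symbols not updated another probe stood for it and the difference was -0.07.

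Between the spleen labels 379 genes changed, 252 higher and 127 lower on the host label, 254 of them at least 2-fold, with 2915 at unadjusted p < 0.05. Groups of 2 arrays separated 6964 genes (54.8%), against 33.3% from chance order. Centring the values gave 336 genes, 151 higher and 185 lower, of which 269 were among the 379, and moved the median difference over all genes from -0.03 to -0.17. With only these groups in the model 7 genes passed, and leaving out 1 array gave from 9 (host spleen 4) to 1542 (wild-type spleen 3).

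The double-positive list rose on the host spleen label in 15 of 16 members (median 1.95, adjusted p = 3.12e-06, or adjusted p = 0.335 with an estimated correlation; 8 adjusted over the list alone). The TCR complex list rose in 13 of 13 (median 1.22, adjusted p = 3.6e-05, or adjusted p = 0.335 with an estimated correlation; 2 adjusted over the list alone). The T lineage factor list rose (12 of 12 higher, median 1.21, adjusted p = 0.000238, or adjusted p = 0.335 with an estimated correlation; 2 adjusted over the list alone), with the chromatin organizer Satb1 at 1.31 (adjusted p = 0.177), as did the DN3 list (12 of 17 higher, median 0.89, adjusted p = 0.0388, or adjusted p = 0.422 with an estimated correlation; 2 adjusted over the list alone). The thymic epithelium list rose in 8 of 10 members (median 0.26, adjusted p = 0.00706, or adjusted p = 0.335 with an estimated correlation; 3 adjusted over the list alone). Of its members, the chemokine Ccl25 was 7.06-fold higher (11.16 ± 0.24 against 8.34 ± 0.49, adjusted p = 0.0334) and the keratin Krt18 at least 1.55-fold higher (adjusted p = 0.0445); with dim values held at the threshold the list median was 0.09. Without wild-type spleen 1 Satb1 differed by 0.62 and the medians were 0.78 for double-positive genes, 0.74 for the TCR complex, 0.46 for T lineage factors and 0.38 for the DN3 list, and without wild-type spleen 3 that of the thymic epithelium list was 0.17.

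Single members of lists that did not pass also rose on the host spleen label. Siglech, a marker of plasmacytoid dendritic cells, differed by 1.06 (adjusted p = 0.0143; above background on 1 of 2 wild-type arrays). The cell cycle inhibitor Cdkn1b was at least 1.91-fold higher (adjusted p = 0.0294) and the T cell surface protein Ms4a4b at least 1.08-fold (adjusted p = 0.0381).

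Lists of other blood cells fell on the host spleen label. The granulocyte list was lower in 13 of 13 members, with median -6.22 (adjusted p = 1.52e-08, or adjusted p = 0.335 with an estimated correlation; 12 adjusted over the list alone). The platelet list was lower in 8 of 8, with median -3.08 (adjusted p = 2.66e-05, or adjusted p = 0.335 with an estimated correlation; 8 adjusted over the list alone), with the platelet chemokines Ppbp and Pf4 at least 16.8-fold and 14.5-fold lower (adjusted p = 0.0945 and 0.0938, not passing), or 8.09-fold and 6.34-fold without wild-type spleen 1. The macrophage list was lower in 16 of 16, with median -2.58 (adjusted p = 2.66e-05, or adjusted p = 0.363 with an estimated correlation), with 0 in limma adjusted over the list alone and Vcam1 at -3.96 (adjusted p = 0.184). The erythroid list was lower in 10 of 10, with median -2.88 (adjusted p = 0.000126, or adjusted p = 0.335 with an estimated correlation; 8 adjusted over the list alone), with Hbb-b1 at -1.23 (adjusted p = 0.664). The mast cell list was lower in 9 of 9, with median -1.31 (adjusted p = 0.000126, or adjusted p = 0.335 with an estimated correlation; 6 adjusted over the list alone), with the histamine-forming enzyme Hdc 7.59-fold lower (adjusted p = 0.0338), or 4.84-fold without wild-type spleen 1. Without wild-type spleen 1 the median of the mast cell list was -0.07 and that of the macrophage list -1.43, with Vcam1 at -2.71.

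Stromal and progenitor lists fell as well. The endothelium list was lower in 9 of 10 members, with median -1.57 (adjusted p = 7.84e-05, or adjusted p = 0.335 with an estimated correlation; 7 adjusted over the list alone), with the vessel factor Egfl7 7.89-fold lower (adjusted p = 0.0443). The fibroblast list was lower in 11 of 12, with median -1.81 (adjusted p = 0.00159, or adjusted p = 0.335 with an estimated correlation), with Fbln1 at -2.15 and 0 members passing in limma adjusted over the list alone. The DN1-DN2 list was lower in 14 of 15, with median -1.54 (adjusted p = 3.6e-05, or adjusted p = 0.335 with an estimated correlation; 10 adjusted over the list alone), with Fcer1g, which myeloid cells also make, at -3.81 (adjusted p = 0.137). MYC targets had median -0.73, with 14 of 16 lower (adjusted p = 0.00986, or adjusted p = 0.535 with an estimated correlation; 1 adjusted over the list alone). The plasma cell list was lower in 6 of 7, with median -0.63 (adjusted p = 0.00986, or adjusted p = 0.335 with an estimated correlation; 3 adjusted over the list alone), with Mzb1 at -3.79 (adjusted p = 0.191). With dim values held at the threshold the medians of the endothelium, mast cell and fibroblast lists were -1.31, -1.12 and -1.56. Without wild-type spleen 1 they were -0.91 for endothelium, -0.56 for fibroblasts, -0.40 for DN1-DN2 genes and -0.04 for plasma cells, with Mzb1 at -1.40 and Fcer1g at -2.75. Without wild-type spleen 3 the MYC median was -0.42 and Fbln1 differed by -0.81.

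Arrays of one label differed widely in lineage genes. Over single genes the median SD was 0.223 in grafts, 0.244 in T-ALL, 0.172 in T-ALL marked Rag-, 0.255 in wild-type thymus, 0.255 in wild-type spleen and 0.0849 in host spleen. The granulocyte list ranged from 6.81 to 10.23 over the 4 grafts, and the erythroid list from 8.90 to 12.27 over T-ALL 1 to 7. The TCR complex list ranged less in T-ALL, from 11.18 to 11.53.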

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

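The tests of labels and mixing, the test of erythroid RNA and the regroupings of T-ALL marked Rag- were chosen after the result had been seen; the test of Tal1 with erythroid genes as covariate, the pancreas test and the regroupings of T-ALL and grafts were chosen before.

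Single arrays stood far from the others of their label for 17 of the 102 groups of values checked, where the rule used marks about 1 in 20 groups by chance, a rate that holds for independent groups and was not simulated for these, which share arrays. Thymus graft 3 accounted for most. Its fibroblast list stood at 9.44 (7.59 to 7.75 on the other grafts), endothelium at 8.65 (7.27 to 7.44), platelet at 8.99 (6.85 to 7.01), MYC targets at 11.27 (9.77 to 10.01), Notch at 9.26 (8.01 to 8.17), apoptosis at 9.27 (9.83 to 9.90), tumour suppressors at 9.15 (9.46 to 9.48) and the TCR complex at 11.19 (12.17 to 12.34). Its Hes1 was 9.24 (7.03 to 7.25), Mki67 12.54 (9.64 to 9.72), Myc 8.40 (7.21 to 7.40) and Cd8b1 14.23 (14.90 to 14.96). Thymus graft 2 stood apart in the single-positive list at 9.53 (8.06 to 8.15), the cytotoxic list at 8.69 (7.43 to 7.44), NK cells at 8.68 (7.50 to 7.64) and interferon at 9.25 (7.78 to 7.96). T-ALL 4 stood apart in the single-positive list at 9.07 (8.24 to 8.56). The nearest array to graft 3 was T-ALL marked Rag- 8 (r = 0.980), and the cause was not tested.

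Thymocyte genes were high on the arrays labelled host spleen and low on wild-type thymus 1. A mislabelled sample would give this: wild-type thymus 1 correlated better with its nearest spleen-labelled array than with wild-type thymus 3, by 0.0820, but this test was chosen after the pattern and the data do not show which labels would be exchanged. That nearest array was wild-type spleen 1, and whether it shows normal spleen is itself in doubt. Likeness to it therefore does not settle an exchange. Thymocytes mixed into otherwise normal host spleens would dilute the granulocyte list slightly, whereas that of the host arrays lay 4.05 below the wild-type spleens. This speaks against mixing only if the wild-type spleen arrays show normal spleen, which is in doubt. Their B cell lists stood at 7.83 and 7.18, within the range of all arrays. The double-positive list of wild-type spleen 3, 10.65, lay above that of wild-type thymus 3, 10.21. The gap therefore cannot settle mixing. Spleen cells mixed into wild-type thymus 1 could lower its TCR list, which was lower by 2.38 (-2.38) than on wild-type thymus 3, but so could an exchange. At 8.87 the list also lay below wild-type spleen 1 (10.03) and 3 (11.29), where a mix of such cells with thymocytes would lie between. This is 1 array, and the spleen arrays are themselves in doubt, so mixing was not settled. Thymocyte-like cells sorted from or filling the host spleens could not be told from thymus by the epithelial list, whose median difference was 0.065; this was the last of several versions tried, after the B cell list (-0.345, with 4 of 11 genes above background) and the epithelial mean (0.54, or 0.204 without Ccl25).

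Tal1 and Lmo2 varied between arrays together with erythroid genes, a relation that for Tal1 was not taken within a label. RNA of erythroid cells in the preparations may explain this, since Tal1 followed the erythroid list with r = 0.971. The platelet list did almost as well (0.896 for Tal1 and 0.944 for Lmo2), so other blood cells are not excluded. Higher Tal1 in the T-ALL was not shown with or without the erythroid list as a covariate: the difference from grafts was -0.28 (SE 0.32) with it and 0.86 (SE 0.78) without it, with Tal1 above background on only 4 of 7 T-ALL arrays and 2 of 4 grafts. With that covariate 6 genes changed between T-ALL and grafts, all of them also changed without it. 

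Digestive enzyme genes were high on some arrays, with Amy2a5 above 10 on 6 arrays, at 9.85 on thymus graft 3 and at most 7.47 on the others. Of 18 acinar genes, 11 were above background on graft 3. Amy2a5 was 14.51 and 14.58 on wild-type spleen 1 and 3, 13.76 on wild-type thymus 1, 13.90 and 13.54 on T-ALL marked Rag- 8 and 10 and 12.14 on T-ALL 7. Pancreas tissue carried along in these preparations may explain this, since Cpb1, Cela3b and Cel each followed Amy2a5 with r of at least 0.952 (0.960, 0.952 and 0.968). How it would reach arrays of T-ALL and thymus was not tested.

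Regrouping the arrays of T-ALL and grafts gave as many changed genes as the labels in 4 of 100 splits, the labelled one included, and up to 985 against 41. The split with the most genes set grafts 1, 2 and 4 together with T-ALL 1, 4, 5 and 7, which points to a structure among the samples other than the labels. For T-ALL marked Rag- against T-ALL the labels gave 0 changed genes, so that 100 of 100 splits had to give as many (the highest other gave 9), and this regrouping tests nothing.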

How the results depend on the processing

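Background-subtracted and centred values, robust moderation, symbols without update, the omission of doubted arrays, the lists on single chips and the list medians and folds of named genes without single arrays were chosen after first results had been seen, and the others before. Counts of changed genes moved widely, and of 50 results for named genes that changed only 1 kept its call under every alternative chosen beforehand other than leaving out an array. Of the results for named genes that had not changed, 19 passed under at least 1 setting. Only Slamf6 in host against wild-type spleen changed direction among genes that had passed (-0.07 without the symbol update). Fgf13 in T-ALL against grafts passed in 23 of 25 settings. The causes were not tested. Processing of values before normalization, detection p values and median centring in place of quantile normalization were not run.

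For T-ALL against grafts, 41 genes became 23 at 2-fold, 16 without the filter, 26 with mean probes, 165 with array weights, 17 with chip as a random block, 20 without the symbol update, 19 with robust moderation and 24 with only those groups. Chip as a fixed block gave 0 in limma (1824 at unadjusted p < 0.05), chip 1 gave 5, chip 2 gave 0 (777 at unadjusted p < 0.05) and pooled T-ALL 224, with 35 of the 41 shared. Background-subtracted values gave 54 (26 higher, 28 lower), centring 54 and the stricter filter 56. Leaving out 1 array gave 2 to 1109: 2 without graft 1 or graft 4, 26 without graft 2, 1109 without graft 3 (438 higher, 671 lower, including all 41), and 19, 48, 17, 8, 9, 9 and 13 without T-ALL 1 to 7.

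For grafts against wild-type thymus, 10 became 3 with background-subtracted values, 6 with mean probes, 0 in limma with array weights (1172 at unadjusted p < 0.05), 279 with chip as a random block, 2 with only those groups and 139 without graft 3 and wild-type thymus 1. Leaving out 1 array gave 1 to 1437: 1, 5, 1104 and 4 without grafts 1 to 4, and 1437 without wild-type thymus 3; without wild-type thymus 1 it was 11, of which 2 were shared. For T-ALL against wild-type thymus, 4 became 0 in limma with background-subtracted values (1723 at unadjusted p < 0.05), array weights (714) or only those groups (1459), 17 with chip as a random block and 2 with T-ALL pooled. Leaving out 1 array gave 0 to 1313: 1, 12 and 0 (1507 at unadjusted p < 0.05) without T-ALL 1, 3 and 5, and 7 and 1313 without wild-type thymus 1 and 3. Their overlap of 4 became 0 with background-subtracted values. In both comparisons the count with chip as a random block rests on a negative correlation within chips (-0.12) and does not allow for chip.

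For T-ALL marked Rag-, 0 became 13 with chip as a fixed block and 1 without Rag- 10. For wild-type thymus against spleen, 0 became 7 and 207 without thymus 1 and 3 and 12 and 157 without spleen 1 and 3. A block for the numbers 1 and 3 gave 0 in limma (618 at unadjusted p < 0.05). Deviations of like-numbered arrays from their group means correlated at r = 0.680. With 2 arrays per group these deviations are mirror images, so both pairs had to give the same value and it counts once. With no word of shared mice in the labels the arrays share only numbers. For host against wild-type spleen, 379 became 212 without the filter, 132 with array weights, 238 with chip as a random block and 7 with only those groups. Leaving out 1 array gave 9 to 1542: 9 and 19 without host spleen 4 and 5, 58 and 1542 without wild-type spleen 1 and 3.

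Lists changed in number from 9, 14, 11, 2, 8 and 15 in the comparisons as ordered above to 0 in each with an estimated correlation, where the smallest adjusted p were 0.404, 0.372, 0.399, 0.945, 0.402 and 0.335. The rotation test gave 2, 2, 0, 0, 0 and 0. For T-ALL against grafts chip as a fixed block gave 11, chip 1 alone 16 and chip 2 alone 7, and the interferon list fell on chip 1 (adjusted p = 0.0179) but rose on chip 2 (adjusted p = 0.000556). For T-ALL marked Rag-, centring gave 1 and chip 3 alone 6.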

Other observations

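The TCR segments, kidney genes and pairs of arrays given here were chosen after their values had been seen.

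Of 16 TCR alpha and beta variable segments, 16, 14, 4 and 15 were above background on thymus grafts 1 to 4. On T-ALL 1 to 7 they numbered 11, 6, 4, 11, 11, 3 and 6, on T-ALL marked Rag- 6, 3 and 4, on host spleens 4 and 5 10 and 11, on wild-type thymus 1 and 3 3 and 4, and on wild-type spleen 1 and 3 5 and 4. Trbv13-1 was 12.77, 12.58 and 13.21 on grafts 1, 2 and 4, 12.00 and 12.09 on the host spleens and 6.97 on graft 3. Trbv1 was 10.87, 10.02 and 11.34 on grafts 1, 2 and 4, 10.94 and 10.78 on the host spleens and 6.95 on graft 3.

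Thymus grafts 1 and 4 correlated at r = 0.994, with 10 genes more than 2-fold apart, and Xist, expressed from the inactive X chromosome, at 10.18 and 9.42. Host spleens 4 and 5 were as close (r = 0.993, 10 genes more than 2-fold apart) with Xist at 11.40 and 6.67, so correlations this high also occurred between arrays of unlike Xist level. The B cell list lay between 7.07 and 7.83 on all 20 arrays, those labelled spleen included.

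The kidney transporter gene Slc34a1 was 11.30 on graft 2 and 9.84 on T-ALL 4, and the kidney enzyme gene Miox 11.03 and 9.87. On T-ALL 1 they were 7.76 and 7.99, and on T-ALL 5 7.48 and 7.61.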
